A study of Mus musculus with 2 samples.

How the data were processed

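RNA from splenic CD4 T cells of C57BL/6 mice, cultured under Th9 or Th9+IFNgamma conditions, was measured on 2 single-colour arrays, 1 per condition. Per the labels, the cells were sorted magnetically, cultured for 5 days in all, and lysed for total RNA, of which 500 ng was amplified and labelled with Cy3. Groups were taken from the culture condition in the labels. The labels give no number of mice behind a culture. Both arrays lay on the same slide and were read in the same scan, so slide and scan did not differ between the conditions.

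The scanner intensity values were made by the authors with Agilent Feature Extraction 10.7.3.1, per the file headers, and the submitters' processing notes name version 10.7. The processed intensity is background-subtracted and detrended inside each array, per the file headers, and it was deposited without scaling between arrays. Each array has 45018 spots, of which 43379 are not controls, for 41174 probes, and 245 probes are printed 10 times. The flags deposited beside the intensities mark spots well above background, saturated spots and outliers. Outlier flags fell on 99 spots of the Th9+IFNgamma array and 71 of the Th9 array, and no spot was saturated. A second table deposited by the authors holds log2 values. Set against the scanner values, each of its columns was log2 of the median processed signal over a probe's spots minus the array's 75th percentile, with a constant offset for all 41174 probes (SD of the offset 2.5e-07 and 2.2e-07). Its column medians were -4.05 for Th9+IFNgamma and -3.93 for Th9, so that its scale, centring and direction are known, and it served as an alternative source of values.

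Probe names carry a RefSeq accession in the scanner output, which was matched without version to a table of mouse RefSeq genes of the GRCm38.p6 assembly. Of 41174 probes, 27050 (65.7%) matched 1 gene, 0 matched several and 14124 matched none, which gave 18434 named genes. Unnamed probes stayed out of the gene counts. Of the unnamed, 5602 were well above background on both arrays, with 257 at least 2-fold higher and 319 at least 2-fold lower in Th9+IFNgamma. The array headers name a different genome build from that table, so no coordinates are given.

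In the main setting, log2 of the processed signal was averaged over the spots of a probe, and the array's 75th percentile was subtracted (631.9 for Th9+IFNgamma and 567.0 for Th9 on the linear scale, a ratio of 1.11). Control spots and 3 probes called outliers were left out. A gene's value is that of its brightest probe among those well above background on both arrays (23628 probes, 12272 genes). Scaled signals are linear values after both arrays were brought to a common 75th percentile of 598.6, and they compare the same gene between arrays, never different genes. A fold is the higher over the lower scaled signal. Of 4415 genes with several measured probes, 3420 had probes that all agreed in sign, as did 392 (96.1%) of the 408 such genes that were at least 2-fold apart, and in 275 of these every probe reached 2-fold. A gene whose probes were well above background on 1 array only has a bound, written as at least N-fold. It is the bright array's signal over the higher of the dim probe's own signal and the lowest signal well above background on the dim array. There were 471 such genes on the Th9+IFNgamma array and 484 on the Th9 array.

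With 1 array per condition no test was possible, and no p-value, standard error or adjusted value is given. Differences are described against a 2-fold threshold. The number of arrays limits the precision. As a yardstick of spot noise, single spots of 144 probes printed 10 times gave an SD of the log2 difference of 0.14 (1365 spots, central 95% from -0.27 to 0.27), namely 0.29 for signals below 64, 0.09 from 64 to 1024 and 0.05 above. The error that the extraction software attached to the log2 difference of 108 named genes was 0.20 to 0.36. Over all genes the log2 signals of the arrays correlated with r = 0.97, across genes, which are not independent replicates.

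Before the data were examined, 34 gene lists with 599 entries were fixed, covering helper T cell lineages, interferon and cytokine responses, antigen presentation, metabolism, cell cycle and markers of other cell types, and 575 entries had a named probe. Some genes stand in several lists. Each list is described by its members at least 2-fold apart, its median log2 difference, and, with at least 5 measured genes, the percentile of that median among 10000 random lists of the same size drawn from 20 bins of mean signal. These percentiles describe these 2 arrays and are no test of the cultures. The genes named in the text follow a rule also fixed beforehand. It takes the 12 largest differences in each direction among genes whose probes agree in sign, the 5 largest bounds in each direction and 15 genes chosen in advance, among them Ifng, Tbx21, Eomes, Runx3, Irf1, Il9, Spi1, Irf4, Gata3, Il4, Il5, Il13 and Foxp3. From each list it takes up to 4 members with the largest difference of at least 2-fold, or up to 2 where none reached it. Genes named outside the rule were chosen after their values were seen, and some genes that the rule takes are not reported here.

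The alternatives fixed beforehand were normexp background correction with an offset of 50, scaling to the median, quantile normalization, loess on mean intensity, a 75th percentile over detected probes, the authors' table, 3 other filters on dim probes, 2 other rules for genes with several probes, 2 treatments of saturated and outlier spots, thresholds of 1.5-fold and 3-fold, and random lists not matched on signal. Normexp was planned on mean spot signals and was run on median spot and background signals, the columns used here. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 were used.

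The procedure was tested on simulated data with the spot noise of these arrays. Over 12763 genes, 50 of 50 planted 3-fold higher and 50 of 50 planted 3-fold lower genes were called at the 2-fold threshold, as were 0 of 50 genes planted 1.5-fold higher, 2 of 50 planted 1.5-fold lower and 1 of 12563 unchanged genes. Of 200 random lists of 20 unchanged genes, 9 (4.5%) fell outside the central 95%. The simulated arrays held spot noise only, with none of the variation between mice, cultures or labelling reactions, and shared 1 set of detection flags. The random lists came from the same genes that they were compared with. These counts therefore check the procedure and do not give the share of false 2-fold calls between cultures.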

Results

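The series measured gene expression in CD4 T cells from the spleen of C57BL/6 mice, an inbred laboratory strain, after 5 days of culture under 2 cytokine conditions. The cells had been purified by magnetic sorting to over 98% and stimulated for 2 days through the T cell receptor and CD28, then cultured for 3 more days. The Th9 culture held IL-4 at 10 ng/ml, TGF-beta at 3 ng/ml and an antibody against IFN-gamma at 1 µg/ml, a mixture that directs T cells towards production of IL-9. The Th9+IFNgamma culture held IL-4 at 3 ng/ml, TGF-beta at 3 ng/ml and IFN-gamma at 10 ng/ml. The cultures therefore differed in 3 labelled ways, namely added IFN-gamma, the dose of IL-4 and the antibody. Each condition was measured on 1 single-colour array, so no value below has a replicate, and differences are described by size without a test. Of 41174 probes, 60.6% were well above background on the Th9+IFNgamma array and 59.9% on the Th9 array, and no spot was saturated.

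By its title, the study asked about Th1 cell development under the joint action of IL-4 and TGF-beta, and the comparison that its 2 arrays allow is Th9+IFNgamma against Th9. The Th9+IFNgamma array showed higher signals of Th1 genes, of interferon-response genes and of genes for MHC class I antigen presentation, and lower signals of Th2 and Th17 genes. Tbx21, which encodes the Th1 transcription factor T-bet, was 36.1-fold higher, and Eomes, a related T-box factor, was 28.2-fold higher. Il9 was 10.5-fold lower, Il4 21.4-fold lower and Il17f 80.9-fold lower, where normexp background correction moved the log2 difference of Il17f from -6.34 to -4.50. Among 12272 genes well above background on both arrays, 632 (5.15%) were at least 2-fold higher and 910 (7.42%) at least 2-fold lower in Th9+IFNgamma, while 10730 lay within 2-fold. With median scaling 772 were higher and 776 lower, so the excess of lower genes depends on the scaling. It remained with quantile normalization (654 higher, 865 lower), with loess on intensity (628 and 900) and with a 75th percentile over detected probes (610 and 940). At least 8-fold differences were found for 52 higher and 96 lower genes. A further 159 genes were detected on the Th9+IFNgamma array alone, and 227 on the Th9 array alone, with a bound of at least 2-fold. With normexp these counts were 39 and 50. The median log2 difference over all genes was -0.01. Single spots of probes printed 10 times on each array gave log2 differences with an SD of 0.14 about their probe's mean, and of 0.29 for signals below 64. This spread covers the printing and reading of spots, and none of the variation between mice, cultures or labelling reactions.

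**Figure D1:**
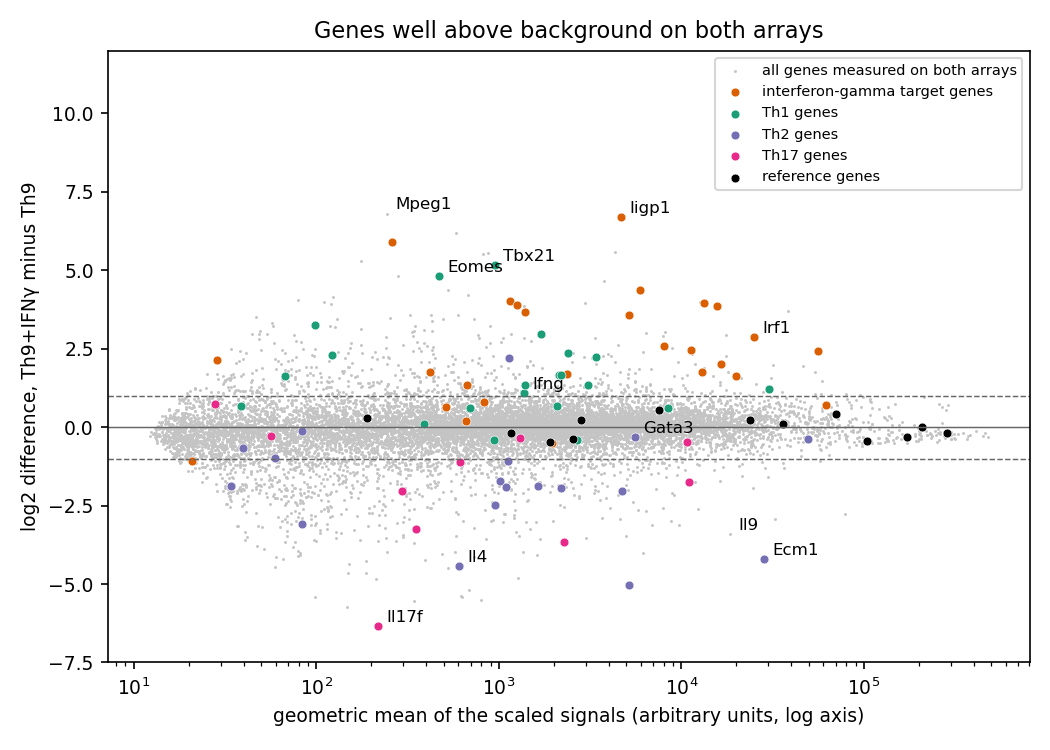
Log2 difference between the arrays (vertical axis, Th9+IFNgamma minus Th9) against the geometric mean of the scaled signals (horizontal log axis, arbitrary units) for 12272 genes well above background on both arrays, each point being 1 gene and dashed lines marking 2-fold. Genes of the interferon-gamma and Th1 lists lie mostly above 0, genes of the Th2 and Th17 lists mostly below 0, and the 13 reference genes all lie within 2-fold.

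In the main setting, the 12 largest differences towards Th9+IFNgamma, among genes measured on both arrays whose probes had the same sign, were led by Mpeg1, which encodes the pore-forming protein perforin-2 (112-fold), and Iigp1, an interferon-inducible GTPase (103-fold). They also held Ly6c1 (72.4-fold), Gbp7 (59.8-fold), Isg20, an interferon-induced exonuclease (48.1-fold), Rtp4 (46.6-fold), Ifi204 (46.1-fold), Nacc2 (39.5-fold), Tbx21, Eomes, Ifit3 (27.9-fold) and Ms4a4b (25.3-fold). With normexp background correction the log2 difference was 4.86 for Mpeg1 (6.81 in the main setting), 5.15 for Ly6c1, 4.33 for Gbp7, 4.95 for Rtp4, 3.58 for Nacc2, 4.04 for Eomes and 3.70 for Ifit3, so that Mpeg1 no longer led. Ifi204 had 3.98 by its probe with the smallest difference. Mpeg1 was read by 1 probe at scaled signals of 2592 and 23.1, and its other probe, detected on the Th9+IFNgamma array alone, gave at least 2.87-fold (a log2 bound of 0.51 with normexp). Apol7c, detected on the Th9+IFNgamma array alone, was at least 196-fold higher. The other large bounds were at least 61.7-fold for Calhm6, 32.9-fold for Oasl2, 29.8-fold for Cyp3a44 and 29.6-fold for Ubd, a ubiquitin-like modifier induced by cytokines. With normexp these bounds were 32.3-fold for Apol7c, 11.2-fold for Calhm6, 5.97-fold for Oasl2, 5.08-fold for Cyp3a44 and 6.16-fold for Ubd.

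The 12 largest differences towards Th9 in the main setting were led by Il17f, a cytokine of the IL-17 family (80.9-fold lower in Th9+IFNgamma). Next came Rnf152 (53.0-fold lower), the membrane protein genes Tmem176a (46.5-fold lower) and Tmem176b (42.0-fold lower), Gatm, an enzyme of creatine synthesis (45.8-fold lower), and Ctsf, which encodes cathepsin F (43.0-fold lower). The others were Map3k20 (42.5-fold lower), Mgll, which encodes monoacylglycerol lipase (36.2-fold lower), Plcd1 (33.0-fold lower), Gad2 (28.4-fold lower), Tg (28.1-fold lower) and Il1r2, a decoy receptor for IL-1 (25.2-fold lower). With normexp the log2 differences were -4.50 for Il17f, -3.76 for Rnf152, -4.45 for Tmem176a, -4.58 for Tmem176b, -4.93 for Gatm, -4.80 for Ctsf, -3.13 for Map3k20, -3.61 for Gad2 and -3.44 for Il1r2. Of the genes detected on the Th9 array alone, Enpp2, which encodes autotaxin, was at least 81.0-fold lower in Th9+IFNgamma. The bounds for Sln, Prss46 and Ppp4r4 were at least 34.7-fold, 26.6-fold and 25.3-fold. With normexp the bounds were 13.6-fold for Enpp2, 6.97-fold for Sln, 5.05-fold for Prss46 and 5.64-fold for Ppp4r4.

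Of 21 measured Th1 genes, 14 were at least 2-fold higher in Th9+IFNgamma and none was at least 2-fold lower. Their median log2 difference was 1.36, above the medians of all 10000 random lists matched on signal, whose central 95% ran from -0.23 to 0.25. Besides Tbx21 (scaled signals of 5684 against 158) and Eomes (2486 against 88.3), Il18rap, a subunit of the IL-18 receptor, was 9.58-fold higher and the chemokine receptor gene Cxcr3 7.88-fold higher. Ifng itself was 2.11-fold higher (2005 against 951). Its 2 probes gave log2 differences of 1.08 and 0.96, so that only 1 of them reached 2-fold. Runx3, which encodes a transcription factor that acts with T-bet, was 1.61-fold higher, within the 2-fold limit. Ccl3, named after its value was seen, was detected on the Th9+IFNgamma array alone, at least 3.52-fold higher.

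Th2 genes went the other way. Of 18 measured, 12 were at least 2-fold lower in Th9+IFNgamma and 1 at least 2-fold higher, with a median of -1.87, below all random lists (-0.29 to 0.25). Plcd1 was 33.0-fold lower, Il4 21.4-fold lower (130 against 2787), Ecm1, an extracellular matrix protein expressed by Th2 cells, 18.6-fold lower, and Rnf128, a ubiquitin ligase, 8.57-fold lower. Il5 was detected on the Th9 array alone, at least 8.05-fold lower in Th9+IFNgamma. Il13 was dim on both arrays (31.5 and 50.3) and 1.59-fold lower. Gata3, which encodes the Th2-determining transcription factor, lay within 2-fold, at 4982 against 6188 (1.24-fold lower). The 1 Th2 gene higher was Gfi1, a transcriptional repressor (4.59-fold, named after its value was seen).

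The Th9 list was mixed. Of 12 measured genes, 5 were at least 2-fold lower and 3 at least 2-fold higher in Th9+IFNgamma, and the median of -0.78 lay below all random lists (-0.25 to 0.33). Il9 was 10.5-fold lower, at a scaled signal of 5661 against 59619, and remained well above background on the Th9+IFNgamma array. Il10, which encodes an anti-inflammatory cytokine, was 11.9-fold lower, and the chemokine receptor gene Ccr6 9.44-fold lower. Batf, an AP-1 family factor (3.39-fold), and Smad3, a mediator of TGF-beta signals (2.78-fold), were the other genes at least 2-fold lower, both named after their values were seen. Irf4, a factor required for IL-9 production, was 1.72-fold lower. Id3, an inhibitor of basic helix-loop-helix factors, was 7.79-fold higher. Irf8 (4.02-fold) and Cd96 (4.0-fold) were also higher, these 2 named after their values were seen. Irf8 belongs to the interferon-gamma target list too, and Id3 to the TGF-beta response list. Il1rn was detected on the Th9 array alone, at least 13.3-fold lower in Th9+IFNgamma. Spi1, which encodes PU.1, was not well above background on either array.

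**Figure D2:**
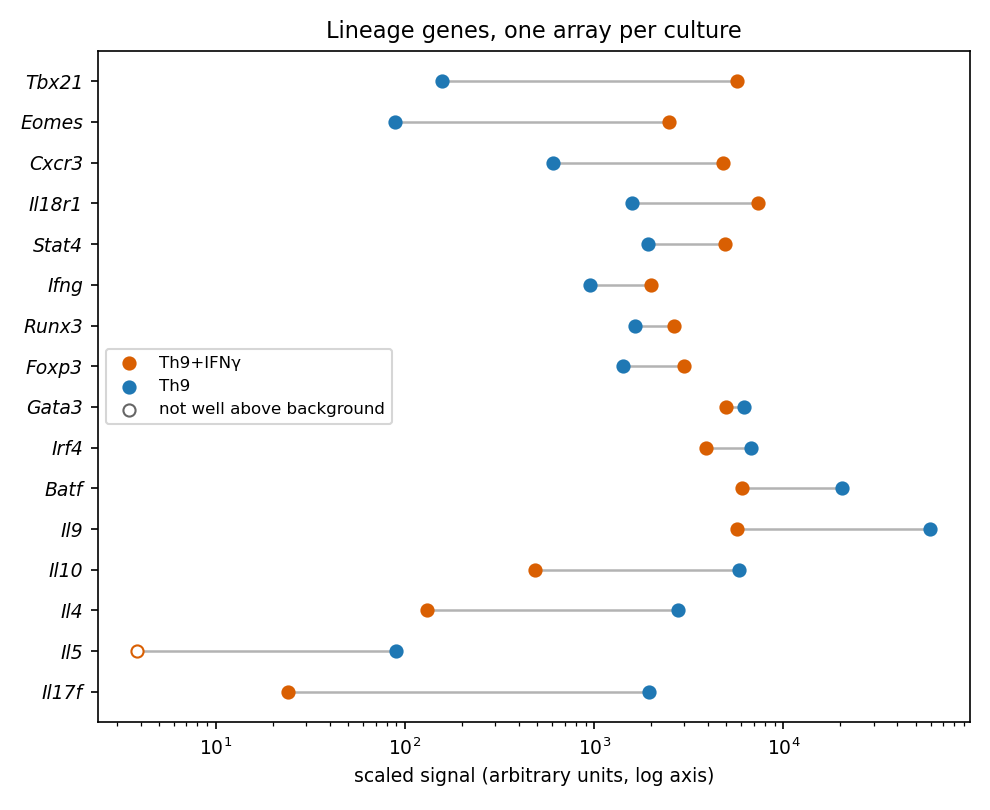
Scaled signals (horizontal log axis, arbitrary units) of 16 lineage genes on the Th9+IFNgamma array and the Th9 array, 1 array per culture, with open circles for signals not well above background. Tbx21 lay at 5684 in Th9+IFNgamma and 158 in Th9, whereas Il9 lay at 5661 and 59619, and Gata3 at 4982 and 6188.

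Of 10 measured Th17 genes, 6 were at least 2-fold lower in Th9+IFNgamma and none was at least 2-fold higher, with a median of -1.43 below all random lists (-0.41 to 0.35). Il17f was read at 1948 on the Th9 array and 24.1 on the Th9+IFNgamma array. Ahr, which encodes the aryl hydrocarbon receptor, was 12.6-fold lower, Ccr6 9.44-fold lower and Rora, which encodes a nuclear receptor, 4.06-fold lower. Il1r1, Il21 and Il22, named after their values were seen, were detected on the Th9 array alone, with bounds of at least 10.3-fold, 5.12-fold and 2.08-fold. Il17a and Il23r were not well above background on either array. Ccr6 and Batf belong to the Th9 list too.

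Regulatory T cell genes showed no common direction, with 3 of 16 at least 2-fold higher, 2 at least 2-fold lower and a median of -0.02 at percentile 36.4 of random lists. Foxp3, the factor that defines these cells, was 2.09-fold higher in Th9+IFNgamma, Ikzf2 (Helios) 3.93-fold higher and Entpd1 (CD39) 3.24-fold higher. Nt5e (CD73) was 2.83-fold lower and Tnfrsf9 2.19-fold lower. Of 9 follicular helper genes, 2 were at least 2-fold lower, namely the costimulatory receptor gene Icos (3.29-fold) and the adaptor gene Sh2d1a (3.18-fold), and none measured on both arrays was at least 2-fold higher. Tox, named after its value was seen, was detected on the Th9+IFNgamma array alone, at least 6.15-fold higher. Il21, which stands in the Th17 list too and was also named afterwards, was detected on the Th9 array alone, at least 5.12-fold lower in Th9+IFNgamma. The list median of -0.36 lay at percentile 6.51, and it was -0.65 with signals of at least 100.

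Interferon-response genes had the highest medians among the 29 lists with at least 5 measured genes. Of 26 measured interferon-gamma target genes, 20 were at least 2-fold higher in Th9+IFNgamma and 1 was at least 2-fold lower, with a median log2 difference of 2.27, above all random lists (-0.17 to 0.22). Iigp1 was 103-fold higher (47452 against 460), and the guanylate-binding protein genes Gbp7, Gbp2 and Gbp3 were 59.8-fold, 20.9-fold and 16.4-fold higher. Irf1, an interferon-induced transcription factor, was 7.30-fold higher. Ubd and Cxcl10 (at least 4.49-fold, named after its value was seen) were detected on the Th9+IFNgamma array alone. The 1 gene at least 2-fold lower was Ido1, close to background at 14.4 against 30.2, likewise named afterwards. Of 21 measured type I interferon-stimulated genes, all were higher, 18 of them at least 2-fold, with a median of 2.69 (random lists -0.23 to 0.25). Isg20, Rtp4, Ifit3 and Isg15, a ubiquitin-like modifier (20.8-fold), led this list. Another 6 of its genes, Oasl2 among them, were detected on the Th9+IFNgamma array alone with bounds of at least 2-fold, a size that 3 of them kept with normexp.

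Of 22 genes of the MHC class I pathway, which loads peptides for presentation to CD8 T cells, 12 were at least 2-fold higher in Th9+IFNgamma and 1 was at least 2-fold lower. Their median of 1.04 lay above all random lists (-0.18 to 0.26). H2-T22 was 7.72-fold higher (log2 difference 2.23 by its probe with the smallest difference), H2-Q8 4.87-fold higher and Tapbpl, a peptide-loading factor, 4.71-fold higher, whereas H2-Q1 was 6.12-fold lower. H2 genes are near-identical in sequence, as are members of the Gbp, Ly6c, Ifi200 and Klra families, so that a probe can take up RNA of a relative and single members stay uncertain. Of 11 MHC class II pathway genes, Ciita, the master activator of class II transcription, was 6.01-fold higher and H2-DMa 2.27-fold higher, while the other 9 lay within 2-fold. The class II median of 0.34 lay at percentile 97.4, and over the alternative settings it ranged from -0.08 to 0.46.

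**Figure D3:**
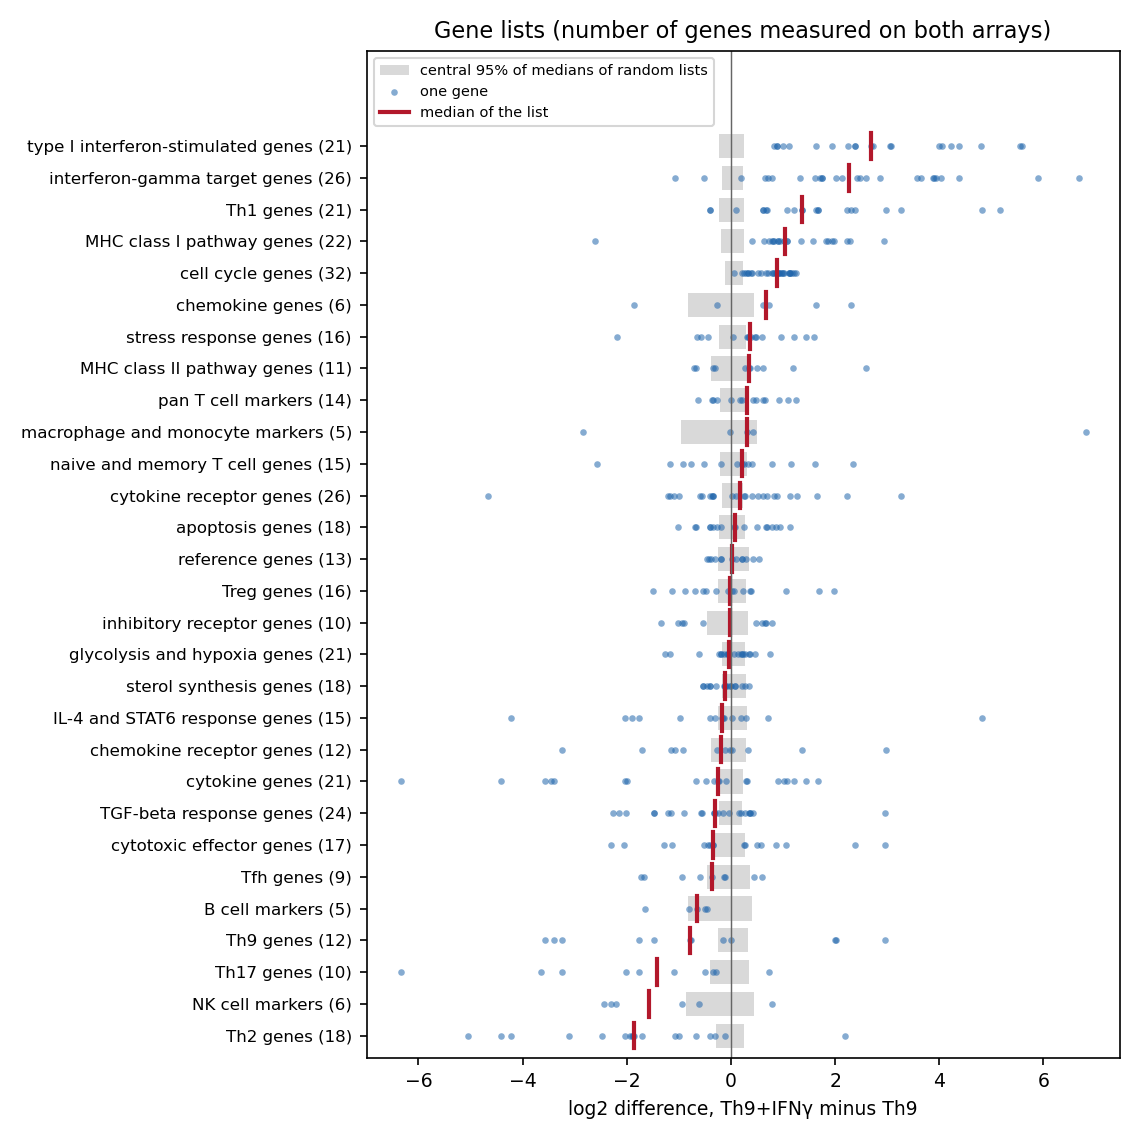
Log2 differences between the arrays (horizontal axis, Th9+IFNgamma minus Th9) for the gene lists with at least 5 measured genes, where each point is 1 gene, red lines are list medians, grey bars hold the central 95% of medians of 10000 random lists matched on signal, and the number of measured genes stands in brackets. The medians run from 2.69 for type I interferon-stimulated genes to -1.87 for Th2 genes.

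TGF-beta, present at the same dose in both cultures, had a response list of 24 measured genes, of which 7 were at least 2-fold lower in Th9+IFNgamma and 1 at least 2-fold higher. The median was -0.31, at percentile 0.80, and -0.14 with signals of at least 100. Ltbp3, which binds latent TGF-beta, was 4.78-fold lower by 1 probe and had a log2 difference of -0.40 by the other. Ccn2, a matrix growth factor, was 4.45-fold lower, and Smad6, an inhibitory Smad, 4.06-fold lower. Id3 was the gene at least 2-fold higher. Of 15 IL-4 and STAT6 response genes, 4 were at least 2-fold lower and 1 at least 2-fold higher, with a median of -0.17 at percentile 7.64. The 4 were Ecm1, the cytokine gene Il24 (4.09-fold), Epas1, a hypoxia-inducible factor (3.72-fold), and Pparg (3.40-fold, named after its value was seen), and the higher gene was Eomes.

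Of 21 cytokine genes, 5 were at least 2-fold higher in Th9+IFNgamma and 7 at least 2-fold lower, with a median of -0.25 at percentile 2.78 (-0.13 with median scaling). Il17f, Il4 and Il10 were followed by Tnfsf14, which encodes LIGHT (176 in Th9+IFNgamma against 1932). The cytokine genes at least 2-fold higher were Ifng and, named after their values were seen, Tnf (3.18-fold), Tnfsf11 (2.71-fold), Lta (2.31-fold) and Ltb (2.03-fold). Among 6 measured chemokine genes, Ccl4 was 4.93-fold and Xcl1 3.09-fold higher and Ccl17 3.64-fold lower, and the median was 0.68 (percentile 99.4, random lists -0.83 to 0.45). That median was 0.39 with normexp and 1.39 when genes detected on at least 1 array were counted. Of 12 chemokine receptor genes, 2 were at least 2-fold higher, namely Cxcr3 and Cxcr6 (2.56-fold), and 4 were at least 2-fold lower, with Ccr6 and Ccr4 (3.28-fold) leading, Cxcr4 (2.21-fold) and Ccr8 (777 against 1633) named after their values were seen, and a median of -0.19 at percentile 17.2 (-0.91 to -0.01 over the alternative settings). Of 26 cytokine receptor genes, 5 were at least 2-fold higher and 4 at least 2-fold lower, with a median of 0.18 at percentile 93.6. Il18rap, Il18r1 (4.68-fold) and Il15ra (3.13-fold) were higher, and Il1r2 was 25.2-fold lower. Ifnar2 (2.41-fold) and Il2rg (2.20-fold) completed the receptors at least 2-fold higher, and Tgfbr3 (2.32-fold), Il7r (2.26-fold) and Il6ra (2.14-fold) the lower ones, all but Il7r named after their values were seen.

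Cytotoxic effector genes went both ways, with 3 of 17 at least 2-fold higher, 4 at least 2-fold lower, a median of -0.35 at percentile 2.14 and a mean of 0.003, of opposite sign to the median. The median was -0.18 without a filter on dim probes. Serpinb9, an inhibitor of granzyme B, was 7.80-fold higher and Nkg7 5.2-fold higher, whereas Klre1 was 4.90-fold lower and Gzmc, which encodes granzyme C, 4.16-fold lower. The others, named after their values were seen, were Gzmm (2.09-fold higher), Gzma (2.43-fold lower) and Crtam (2.18-fold lower). Of 10 inhibitory receptor genes, Lag3 was 2.54-fold lower and Cd160 2.02-fold lower, and the median was -0.02 (percentile 56.2). Of 15 naive and memory T cell genes, 3 were at least 2-fold higher and 2 at least 2-fold lower, with a median of 0.21 at percentile 89.3. Satb1, a chromatin organizer, was 5.92-fold lower and Il7r 2.26-fold lower, while Cd69, an early activation marker, was 5.06-fold higher and Dapl1 3.06-fold higher. Cd27 (2.24-fold higher) was named after its value was seen.

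All 32 measured cell cycle genes had a higher signal in Th9+IFNgamma by their brightest probe, and 9 reached 2-fold (from 7 with quantile normalization to 14 with median scaling). Their median log2 difference of 0.88 lay above all random lists (-0.12 to 0.22). Tyms, which encodes thymidylate synthase, was 2.38-fold higher, the topoisomerase gene Top2a 2.32-fold higher, and the mitotic kinase genes Plk1 and Aurka 2.25-fold and 2.20-fold higher. Bub1, Cdc6 and E2f1, named after their values were seen, each had a second probe of opposite sign (log2 differences of -0.05, -0.60 and -0.03). Stress response genes had a median of 0.37 (percentile 99.5), and 3 of 16 were at least 2-fold higher, namely Chac1 (3.02-fold), Sesn2 (2.72-fold) and Atf3 (2.32-fold). Gadd45a was 4.54-fold lower. Of 21 glycolysis and hypoxia genes, Hk2, which encodes hexokinase 2, was 2.41-fold lower and Hif1a 2.25-fold lower, the rest lay within 2-fold, and the median was -0.03 (percentile 25.1). Of 18 apoptosis genes, Bcl2l11, which encodes the cell death protein BIM, was 2.21-fold higher and Mcl1, which encodes a survival protein, 2.01-fold lower, with a median of 0.07 (percentile 64.3). All 18 sterol synthesis genes lay within 2-fold, with a median of -0.11 (percentile 6.45). The largest were 1.46-fold lower for Msmo1 and 1.45-fold lower for Fdft1, whose other probe had the opposite sign. The 13 reference genes also lay within 2-fold, with a median of 0.02 (percentile 47.6) and a range over the alternative settings of -0.04 to 0.13. Gusb was 1.37-fold lower.

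Markers of T cells and of other cell types were read on the same arrays. Of 14 pan T cell markers, 2 were at least 2-fold higher and 12 lay within 2-fold. Cd247 was 2.13-fold higher, and the list median was 0.31 (percentile 97.1). Cd8a, the 1 measured CD8 marker, stood at 1338 and 1074. The 5 measured B cell markers were all lower in Th9+IFNgamma, with a median of -0.66 (percentile 6.07), or -0.35 with normexp. Blnk, an adaptor of B cell receptor signalling, was 3.13-fold lower, and Cd22 was detected on the Th9 array alone, at least 13.3-fold lower in Th9+IFNgamma. Of 6 NK cell markers, Klra3, Klre1 and Klra8 were 5.42-fold, 4.90-fold and 4.59-fold lower at signals of at most 87.8, Ncr1 was not well above background, and the median was -1.57 (percentile 0.10, random lists -0.86 to 0.44). With normexp that median was -0.64 and these 3 genes lay within 2-fold. Of 5 macrophage and monocyte markers, Mpeg1 was at least 2-fold higher and Adgre1 7.19-fold lower, with a median of 0.31 (percentile 94.1, from -0.01 to 0.44 over the alternative settings), and Cd163 was detected on the Th9+IFNgamma array alone (at least 5.66-fold higher). Lyz2, Itgam, Fcgr1, C1qa and C1qc were not well above background on either array. Among 4 dendritic cell markers, Bst2, which is also interferon-induced, was 2.01-fold higher and the list median was -0.14. Mpo was the 1 granulocyte marker measured on both arrays (25.4 and 37.8, log2 difference -0.58), and Ltf was detected on the Th9+IFNgamma array alone (at least 11.5-fold higher). Of 2 measured mast cell and basophil markers, Fcer1a was 2.22-fold higher (59.2 against 26.7), with a list median of 0.19. Of 2 erythroid markers, Hba-a1 was 2.24-fold higher (120 against 53.4), with a list median of 0.55.

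With 1 array per condition, none of these differences has a replicate check. With normexp background correction, Ccl17, Xcl1, Tnfsf11, Smad6, Klra3, Klra8, Klre1, Cd160, Crtam, Gzmm, Cxcr4, Ccr8, Tgfbr3, Fcer1a, Hba-a1, Mcl1 and Ido1 lay within 2-fold, and the log2 differences of Rnf128 (-1.86), Adgre1 (-1.45), Ccn2 (-1.34), Pparg (-1.15), Ccl4 (1.48), Serpinb9 (1.29) and Il18rap (1.83) came nearer to 0. So did the bounds, which stayed at 2.33-fold for Il5, 3.12-fold for Il1rn, 3.07-fold for Il1r1, 3.28-fold for Cd22 and 2.49-fold for Ltf, and lay below 2-fold for Ccl3, Il21, Il22, Tox, Cxcl10 and Cd163. The bound of Il22 lay below 2-fold under 3 other scalings too. Bst2 did so under 3 other scalings, Il6ra under median scaling, and Ifng, Bcl2l11, Ltbp3, Cd247 and Ifnar2 by their probe with the smallest difference.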

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

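Every alternative here was planned, although normexp was run on median instead of mean spot signals. Of 29 list medians, none that lay outside the central 95% of random lists changed sign. Of 375 alternative medians, 344 moved by less than the SD of single spots (0.14) and 31 moved further, 19 of them towards 0. Some of the 344 could not have moved further. Median scaling shifted all genes alike by 0.11, below that SD. The percentile over detected probes also shifted all genes alike, and their median went only from -0.01 to -0.03. The authors' table rests on the same signals, and the outlier setting concerned 3 probes. The 344 are therefore not a count of tests passed. Of 467 single genes followed, 193 were at least 2-fold apart, and 40 of these came within 2-fold under some alternative, 27 of them with normexp. Among these 193, Bub1 alone changed sign, to -0.051 by its probe with the smallest difference. Normexp gave 437 higher and 582 lower genes, a Th2 median of -1.66 and a type I interferon median of 2.35. It cut the genes detected on 1 array alone with a bound of at least 2-fold from 159 to 39 for Th9+IFNgamma and from 227 to 50 for Th9. It adds an offset, which draws dim signals together, and it also used other spot signals and another background model. The shares of these in the changes were not separated. Counting genes detected on at least 1 array gave medians of 1.63 for Th1, -2.00 for Th17, 2.45 for interferon-gamma and 3.06 for type I interferon genes, as more genes enter. Without a filter on dim probes, 1205 genes were higher and 1788 lower among 18434, with medians of -1.39 for Th2, -1.87 for Th17 and 2.89 for type I interferon genes. With signals of at least 100, 425 genes were higher and 481 lower among 9511, and the medians were -1.76 for Th17, 2.42 for interferon-gamma and 2.38 for type I interferon genes. The mean over probes gave 2.45 for interferon-gamma genes, and the probe with the smallest difference -0.61 for Th9 genes, where the cause was not tested. A 1.5-fold threshold gave 1549 higher and 1901 lower genes, and a 3-fold threshold 262 and 437. Median scaling gave 772 higher and 776 lower genes, and it shifted the median of all genes by 0.11 and the higher share of 2-fold genes from 41.0% to 49.9%. The authors' table gave 632 and 910 genes, as in the main setting. Leaving out saturated spots removed nothing, so it tests nothing. Lists not matched on signal moved 3 of 29 percentiles across the central 95% (MHC class II 97.9, pan T cell 98.5, B cell 2.14). Signals near background limit dim genes, and no replicate could be left out. No paired analysis was possible because each condition has 1 array.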

Other observations

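Most gene families in this part come from a scan of 381 symbol stems after the data were seen. Of these stems, 24 lay above and 18 below the central 95% of random lists. If the genes of a stem varied independently, 9.5 on each side would be expected by chance. Relatives of close sequence need not vary independently, so the excess over that number cannot be read as an effect of the cultures. The Ifi200 family and the ribosomal protein genes were grouped by hand, also after the data were seen. All 9 measured Gbp genes were higher in Th9+IFNgamma (median log2 difference 3.66), as were Ifi204, Ifi209 and Ifi211 of the Ifi200 family (median 4.16), which sense nucleic acids. At least 2-fold higher were 8 of the Gbp genes, or 7 with normexp background correction, which gave log2 differences of 2.63 for Ifi209 and 4.88 for Ifi204. Of 5 Ifitm genes, a family that includes interferon-induced antiviral membrane proteins, 4 were at least 2-fold higher and 1 at least 2-fold lower. Ifitm3 was read at 50639 against 3174. The lower one, Ifitm6, came within 2-fold under other settings, as did Ifitm5 with normexp (0.66). Of 6 Schlafen genes, 4 were at least 2-fold higher, or 3 with normexp, where Slfn9 had 0.85. Slfn1 was 5.53-fold higher and Slfn5 1.46-fold lower. Among 5 Toll-like receptor genes, Tlr2 was 7.11-fold and Tlr6 5.25-fold higher, and Tlr9 was 1.14-fold lower. The directions of these family medians held under all 5 other background and scaling settings. Median scaling, a shift of 0.11 for all genes, could not have reversed them.

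Tetraspanin genes leaned the other way, with 7 of 13 at least 2-fold lower in Th9+IFNgamma and 1, Tspan7, at least 2-fold higher (median -1.05, from -1.07 to -0.91 over the settings). Tspan6 was 7.31-fold, Tspan17 3.70-fold and Tspan4 3.43-fold lower. With median scaling 4 of 13 were at least 2-fold lower, as Tspan3, Tspan13 and Tspan33 came within 2-fold, and with normexp the log2 difference was 0.28 for Tspan7 and -2.25 for Tspan6. Of 7 Klra genes, which encode Ly49 receptors of NK cells and some T cells, 6 were at least 2-fold lower and 1, Klra10, was 2.06-fold higher (median -2.41). With normexp 3 were at least 2-fold lower and none at least 2-fold higher, the median was -0.88, and Klra10 had a log2 difference of 0.08. Klra7 was read at 189 against 1004 and Klra16 at 167 against 978 (log2 difference -2.55, or -1.64 by its probe with the smallest difference), and close sequences keep single members uncertain. All 76 ribosomal protein genes were lower in the main setting, by a median of -0.35 with none at 2-fold, and at least 70 were lower under each other setting. The proteasome subunit genes Psma and Psmb had medians of 0.45 and 0.40, and Psmb9 and Psmb10, which belong to the interferon-induced immunoproteasome, were 3.82-fold and 3.92-fold higher.

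The tests of explanations in the next 3 paragraphs were chosen after the results were seen. The loess, background and scaling settings that some of them use had been fixed beforehand, apart from the spot signals used for normexp. Mpeg1, a gene best known from macrophages, was 112-fold higher in Th9+IFNgamma (log2 difference 6.81, or 4.86 with normexp), although the cells had been sorted for CD4 T cells to over 98%. Macrophages or monocytes in that culture would bring their other transcripts, yet of 10 other markers only 1 was at least 2-fold higher (Cd163, by a bound that lay below 2-fold with normexp). Lyz2, C1qa, C1qc, Itgam and Fcgr1 were not well above background on either array, with a highest scaled signal of 4.14. These 5 were picked when that was already known, so their absence is no separate test. Macrophage markers were not all absent, as C1qb (101 in Th9+IFNgamma against 75.3 in Th9), Csf1r (34.1 against 34.3), Cd14 (26.4 against 21.3) and Adgre1 (25.8 against 186) were detected on both arrays. None of them was at least 2-fold higher in Th9+IFNgamma. A fault of one probe is argued against by the second Mpeg1 probe, which was at least 2.87-fold higher. That argument is weak, as with normexp the log2 bound of this probe was 0.51, below 0.57, which is 2 SDs of dim single spots. That Mpeg1 may be expressed by the T cells themselves under IFN-gamma is a hypothesis, and it was not tested. Culture-to-culture variation stays open.

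Cell cycle genes were higher in Th9+IFNgamma by a median of 0.88, all 32 in the same direction by their brightest probe, while the other probes of Bub1, Cdc6 and E2f1 had the opposite sign. An intensity-dependent trend between the arrays was removed by loess, which left a median of 0.82. The upper limit for random lists was 0.22 in the main setting, where they were already matched on signal, and no random lists were drawn after loess. The lowest median over 5 other background and scaling settings was this same loess value of 0.82, so it adds no separate evidence. Median scaling shifted the median of all genes by 0.11. A shift common to all genes leaves their place against random lists unchanged, so such a setting is no test of the scaling. A candidate explanation is a larger share of dividing cells at harvest, through IFN-gamma, the lower IL-4 dose, the absent antibody or a chance difference in culture density, none of which 1 array per condition can separate.

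Il17f, Il1r1 and Ahr were higher in Th9, although the labels list no IL-6 for that culture. IL-17-type gamma-delta T cells in the Th9 culture would bring Il17a, Il23r, Blk, Sox13, Cd163l1 and a scavenger receptor gene listed as 5830411N06Rik, of which only 1 (Cd163l1, at a processed signal of 18.7) was well above background on that array. Il17a and Il23r belong to the Th17 list too, so their absence was already known when the markers were chosen. Each of these markers was read by 1 probe, so unresponsive probes stay open for those not detected. A sort for CD4 removes most such cells. Median scaling shifted the median of all genes by 0.11, too little to remove the differences of Il17f and Ahr. Over 5 other background and scaling settings the value of Il17f nearest to 0 was -4.50, with normexp, against -6.34 in the main setting. For Ahr it was -3.51, so neither gene came within 2-fold. Il1r1, detected on the Th9 array alone, kept a bound of at least 2-fold under those settings (lowest log2 bound 1.62). It may reflect T helper cells with part of a Th17 profile but no measured Il17a, a hypothesis that these arrays cannot test further, and an unresponsive Il17a probe stays open.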
